A study of Mus musculus with 12 samples.

How the data were processed

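RNA of granulosa cells was measured on 12 single-colour Affymetrix mouse arrays with 45101 probe sets, 3 for each of the groups wild type after PMSG, Inha knockout after PMSG, wild type after PMSG and hCG, and knockout after PMSG and hCG. The samples were put in groups by their titles and characteristics. The values were deposited on a log2 scale after GCRMA, per the submitters' processing notes, and the version of GCRMA was not given in the sources used here. Each probe set was centred on its median over the 12 arrays (largest absolute median 5e-07), a step that the labels do not state. The base of the logarithm was checked on the range of the values: the widest probe set spans 13.3 units, above the 11.1 that a 16-bit scanner allows in natural logarithm units. Array medians lay between -0.0197 and 0.093 and no scaling was added. The table held 0 columns of other samples. Raw scans were not used here.

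Probe sets were named from the annotation table given with the series: 34958 name a single gene and 932 several genes. Of the probe sets that are not controls 9160 name none, and the 64 controls, some of which name a gene, were left out of the tests. The single-gene probe sets name 18194 genes. The comparisons, gene lists, alternatives and a filter were fixed before the data were examined, except for 4 alternatives added later. The filter of the main fit was also set later. The filter fixed before, a log2 value of at least 4 on at least 3 arrays, needs levels and does not apply to centred values. For centred values the plan named the upper 60% by mean over all arrays, with the probe set of the highest mean. A mean of centred values is not a level, so this planned rule was run as an alternative only. The main fit instead took the single-gene probe set with the largest SD over the 12 arrays, without regard to group. A gene was kept if this SD was in the upper 60% of the non-control probe sets (SD at least 0.151). This left 12500 genes, 4850 of them with 1 probe set. A choice by SD favours probe sets that respond. Values of the other probe sets are given for many, but not all, of the named genes where they differed in sign or were smaller.

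A group-means model was fitted to the 12 arrays with limma 3.58.1 in R 4.3.3, with moderated variances. Contrasts were knockout against wild type after PMSG, knockout against wild type after hCG, hCG response in wild type, hCG response in the knockout, and their interaction. In a comparison of genotypes, rose and fell mean higher and lower in the knockout than in wild type. P values were adjusted by the Benjamini-Hochberg method over the genes of each contrast, and a gene was called at an adjusted p under 0.05. The 22 gene lists were tested with camera of limma at the preset correlation of 0.01, adjusted over the lists of a contrast, and again with the correlation estimated from the data. Adjusted p values of lists are those of camera unless fry, another list test of limma, is named. The lists were activin and inhibin signalling, BMP and AMH signalling, FSH-induced preovulatory granulosa genes, preantral and cumulus granulosa genes, LH-induced ovulatory regulators, cumulus expansion and follicle matrix, luteal and progesterone synthesis genes, cholesterol biosynthesis, cell cycle and DNA replication, granulosa identity, Sertoli cell genes, TGF-beta-responsive matrix genes, WNT signalling, apoptosis genes, hypoxia and angiogenesis genes, dissociation and stress genes, and markers of oocytes, leukocytes, endothelium, theca and stroma, surface epithelium and red blood cells. Of the 322 list genes 285 were measured, and the others were not analysed here. For members of a list the p values were also adjusted over that list alone.

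Genes were named by a rule: Inha first, then the 10 largest rises and 10 largest falls of each contrast (5 and 5 for the interaction) with an adjusted p under 0.05, a change of at least 2-fold and, except for the interaction, no overlap between the arrays of the groups. Names of clones were left out. Up to 4 members of each list with the smallest adjusted p followed, further called members of lists where the text describes the list, and a fixed panel of follicle genes in every contrast, of which 16 were measured. The ± sign gives the SE of a log2 fold change or the SD of a group, as stated.

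The labels give no batch. A number in the array names is shared by replicate 1 of both genotypes after PMSG, by replicate 2 of both, and by replicates 2 and 3 of wild type after hCG. The serial numbers fall into 7 early and 5 late arrays, the late ones being replicate 3 of the knockout after PMSG and replicates 2 and 3 of both genotypes after hCG. The mean of the hybridization controls lay between -1.04 and -0.0453 on early and between 0.758 and 1.19 on late arrays. The consensus correlation within a name number was 0.297.

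The scripts were tested on simulated data of 12500 genes, 100 of them changed by a log2 value of 1 and a further 100 by 2. The noise was drawn independently for each gene, without a batch or correlation between genes. At a true log2 change of 1 and of 2, the fit recovered 43 and 89 of 100 for the genotype effect after PMSG (14 false calls), 29 and 84 for that after hCG (7), 31 and 86 for the hCG response in wild type (7), 30 and 89 for that in the knockout (8), and 2 and 55 for the interaction (2). Alternatives changed 1 choice at a time, except that the filter by mean value also chose the probe sets by mean value, and the fit with the name number as a fixed block also kept only 4 arrays. The choices were the filter, the probe sets of a gene, normalization, variance model, array weights, groups in the fit, blocks and covariates from the array names, each array left out in turn, the threshold, and the list test. Shared-array correlations were compared with 100 draws of simulated groups without effect. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.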

Results

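Granulosa cells, the somatic cells that surround the oocyte in an ovarian follicle, were profiled from wild-type mice and from mice lacking Inha, the gene of the inhibin alpha subunit. Inhibins are gonadal hormones that oppose activins and lower the release of follicle-stimulating hormone (FSH) by the pituitary. Mice of 21 days received 5 IU of pregnant mare serum gonadotropin (PMSG), which acts like FSH and brings follicles to the preovulatory stage, for 44 to 46 h. Cells were taken by puncture of antral follicles at that time, or 6 h after a further 5 IU of human chorionic gonadotropin (hCG), which acts like luteinizing hormone (LH) and stands in for the ovulatory surge. The 4 groups of genotype and treatment held 3 samples each, which the labels call independent, and each of the 12 samples was measured on 1 single-colour Affymetrix array. The deposited values were log2 expression values centred on the median of each probe set over the 12 arrays, so that a value gives a difference from this median and no level. Array medians lay between -0.0197 and 0.093. Across genes, which are not independent replicates, the replicate arrays correlated with r between 0.524 and 0.756 in wild type after PMSG, 0.21 and 0.374 in the knockout after PMSG, 0.693 and 0.83 in wild type after hCG, and 0.407 and 0.731 in the knockout after hCG. Replicate 3 of wild type after hCG had the widest spread of values (SD 0.727, against 0.371 to 0.6 on the other arrays). The number of arrays limits the precision. Whether a gene lay above background in a group was not analysed here, so a fold against a group near background is not a ratio of 2 measured levels.

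Inha was lost from every knockout array. Its centred log2 value was 5.71 ± 0.145 (SD, n = 3) in wild type after PMSG and 5.45 ± 0.068 after hCG, against -6.68 ± 1.11 and -7.36 ± 0.0306 in the knockout. The knockout arrays lay between -7.40 and -5.40, the highest being replicate 2 after PMSG, and the wild-type arrays between 5.40 and 5.87. Inha fell by 12.38 ± 0.41 (SE) on the log2 scale after PMSG (adjusted p = 3.96e-08) and changed by -12.81 after hCG (adjusted p = 2.69e-08). Which part of the gene the probe set reads, relative to the deleted part, was not given in the sources used here.

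**Figure D1:**
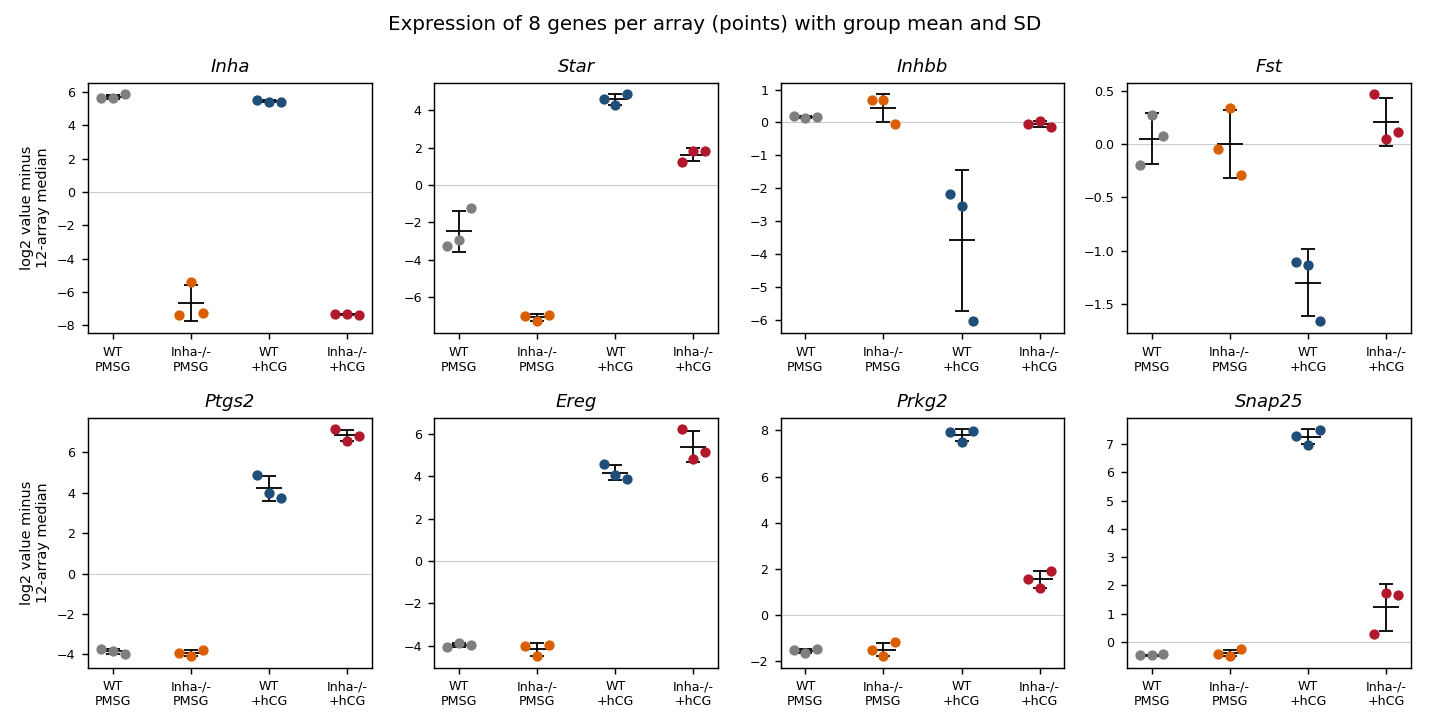
Centred log2 expression (difference from the median of the 12 arrays, vertical axis) of Inha, Star, Inhbb, Fst, Ptgs2, Ereg, Prkg2 and Snap25 in the 4 groups (horizontal axis), where each point is 1 array and the bars give the group mean and SD of 3 arrays. Inha stayed below -5 on every knockout array, and Prkg2 and Snap25 rose less with hCG in the knockout than in wild type.

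The comparison of knockout with wild type after PMSG asks what the loss of inhibin alpha changes in granulosa cells of follicles brought to the preovulatory stage. Single genes of progesterone synthesis were lower in the knockout. Star, which carries cholesterol into mitochondria for steroid synthesis, was 24.2-fold lower (log2 fold change -4.60 ± 0.436, SE, adjusted p = 0.000202, no overlap between the 3 arrays of each group). Without wild-type replicate 3 Star stood at -3.97. Of 26 cell cycle genes 4 were higher, among them the spindle checkpoint kinase Bub1 (3.23-fold). Single transcripts of the oocyte and of theca and stroma cells were higher too, led by the egg-coat gene Zp3 (14.8-fold) and the smooth muscle myosin gene Myh11 (7.32-fold).

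Of the 12 measured luteal and progesterone synthesis genes, 5 fell and 7 did not pass, and 5 fell when adjusted over the list alone. Beside Star these were Cyp11a1, the enzyme of the first step of steroid synthesis (-3.23 ± 0.267, adjusted p = 9.94e-05), its electron donor Fdx1 (-2.34), the prostaglandin F receptor gene Ptgfr (-2.61) and Sfrp4, a secreted WNT-binding protein (-4.53). The other 2 probe sets of Cyp11a1 gave 0.0159 and 0.164, and 1 of the other 4 of Ptgfr gave 0.0154. Ptgfr, at -2.02 without wild-type replicate 3, was no longer called then. The list moved down (median -1.29, camera adjusted p = 5.85e-07, and adjusted p = 0.264 with an estimated correlation). Of the 26 cell cycle and DNA replication genes, 4 rose and 22 did not pass, and 14 rose when adjusted over the list alone. Bub1 rose by 1.69, the cyclin gene Ccne1 by 1.21 and the replication helicase gene Mcm2 by 1.07 on the log2 scale. Bub1 had 0.496 on its other probe set. The list moved up (median 0.614, adjusted p = 2.79e-08, and adjusted p = 0.264 with an estimated correlation).

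Markers of other cell types moved with genotype beside these groups. Of 14 oocyte markers, 7 rose, 7 did not pass and 9 rose when adjusted over the list alone, among them the egg-coat genes Zp3 (3.88), Zp2 (3.65) and Zp1 (2.51) and the oocyte growth factor gene Gdf9 (3.19). Without wild-type replicate 3 Zp3 stood at 2.84, and Zp2, at 2.95, was no longer called. The oocyte list had a median of 2.36 (adjusted p = 3.28e-07, and adjusted p = 0.291 with an estimated correlation). On single arrays the median of the oocyte list lay between 0.70 and 2.05 in the knockout and between -1.37 and -0.596 in wild type. Of 14 theca and stroma markers, 5 rose, 2 fell and 7 did not pass, against 9 and 2 when adjusted over the list alone. The hedgehog transcription factor gene Gli2 rose by 2.73, the smooth muscle actin gene Acta2 by 2.21 and the collagen gene Col1a1 by 2.12, while Cyp17a1, the enzyme of androgen synthesis in theca cells, fell by 2.94 and the retinal dehydrogenase gene Aldh1a1 by 2.35. The other probe set of Myh11 gave 0.0585, and those of Acta2 gave 0.0322 and 0.104. The theca and stroma list moved up (median 1.75, adjusted p = 8.79e-05, and adjusted p = 0.291 with an estimated correlation). Of 9 surface epithelium markers, 4 fell and 5 did not pass, against 7 falls when adjusted over the list alone, with the keratin genes Krt8, Krt18 and Krt19 at -1.58, -1.49 and -1.49 and the uroplakin gene Upk3b at -2.28. This list moved down (median -1.46, adjusted p = 1.1e-06, and adjusted p = 0.264 with an estimated correlation). Leukocyte, endothelial and red blood cell markers did not pass as lists, with medians of 0.44, -0.137 and -0.101 and adjusted p = 0.0888, 0.715 and 0.743. Of 12 dissociation and stress genes 1 fell, the phosphatase gene Dusp1 (-2.12), with 3 when adjusted over the list alone, and the list moved down (median -1.98, adjusted p = 0.000119, and adjusted p = 0.348 with an estimated correlation).

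Smaller downward shifts were found in 3 further lists. In the list of BMP and AMH signalling 2 of 13 genes fell, Bmp2, a growth factor of granulosa cells, by 4.08 and Id1, a transcription regulator induced by BMPs, by 1.69, and 2 fell when adjusted over the list alone (median -0.525, adjusted p = 0.00416, and adjusted p = 0.264 with an estimated correlation). In the list of FSH-induced genes 2 of 13 fell, the kinase gene Sgk1 (-2.03) and Fdx1, with 4 when adjusted over the list alone (median -0.376, adjusted p = 0.00292, and adjusted p = 0.291 with an estimated correlation). In the granulosa identity list 2 of 13 fell, Bmp2 and the steroidogenic factor gene Nr5a1 (-1.47), and 2 when adjusted over the list alone (median -0.413, adjusted p = 0.0261, and adjusted p = 0.291 with an estimated correlation). The other probe set of Nr5a1 gave 0.136. In these 3 lists knockout replicate 3 stood apart from replicates 1 and 2, with medians of -0.727 against 0.0229 and -0.0685 for BMP and AMH signalling, -0.531 against 0.12 and 0.0759 for FSH-induced genes, and -0.506 against 0.161 and 0.338 for granulosa identity. This array has a late serial number and got the lowest of the 12 array weights, 0.291. Without it the adjusted p was 0.0183 for the BMP and the FSH-induced list and 0.146 for granulosa identity, which did not pass then. The remaining 13 of the 22 lists did not pass, and the activin list held no called gene: the activin subunit genes Inhba and Inhbb had log2 differences of 0.34 and 0.28 (adjusted p = 0.684 and 0.886). The activin list had a median of 0.0606, a mean of -0.133 and a downward test direction (adjusted p = 0.888). Of the fixed panel of 16 follicle genes, 11 did not pass, from Amh (-1.67, and -0.53 without wild-type replicate 1) to the EGF-like growth factor gene Btc (0.50), with Inhba, Inhbb, Fst, Fshr, Pgr, Ptgs2, Ereg, Has2 and Ptx3 between them. Beside Inha, Star and Cyp11a1, the genes that passed were Tnfaip6 and Adamts1. The group mean of Tnfaip6 was -3.36 in the knockout and -4.44 in wild type, and that of Adamts1 -1.50 and -0.0796.

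The largest rises were those of Hhip, an antagonist of hedgehog ligands (5.37), the FGF receptor gene Fgfr4 (5.15), the adenylyl cyclase gene Adcy7 (4.94), Srpx2 (4.79) and the retinol carrier gene Rbp4 (4.59). The other 4 probe sets of Fgfr4 gave 0.0959 to 2.07. After Inha, the largest falls were those of the extracellular matrix genes Coch (-6.02) and Comp (-5.55), of Tnfsf11, the ligand RANKL (-5.08), and of Lrp11 (-5.01) and Tulp2 (-4.96). Tnfsf11 lay at -1.09 on knockout replicate 1 and at -3.55 and -3.66 on replicates 2 and 3, so its place in this order depends on single arrays.

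In limma, 373 of 12500 genes were higher and 401 lower in the knockout after PMSG at an adjusted p under 0.05, of which 312 and 350 changed at least 2-fold. The 3 arrays of each group did not overlap for 25.6% of the genes, where chance gives 10%. The arrays of replicate 1 of both genotypes carried the same number in their array names, as did those of replicate 2, and the labels do not state what it marks. The mean of the 18S rRNA controls was alike within these pairs, -2.21 and -2.37 in replicate 1 and 2.39 and 2.18 in replicate 2. On replicate 3, which shares no number, it was 0.828 in wild type and -0.79 in the knockout. The list medians within the pairs were -0.436 and -1.06 for luteal genes, 0.985 and 0.351 for the cell cycle, 1.27 and 3.30 for oocyte, 1.27 and 2.22 for theca and stroma, -1.51 and -0.568 for epithelium, -1.96 and -1.81 for stress genes, and -0.399 and -0.0963 for BMP signalling. The FSH-induced list had medians of -0.668 and 0.0539 and the granulosa identity list of -0.174 and 0.0254, so that neither held its direction in both pairs. With this number as a fixed block over these 4 arrays, a fit with 1 residual degree of freedom, limma called 0 genes, with 1654 at an unadjusted p under 0.05. As a random block over all 12 arrays the number gave 545 higher and 561 lower, all 774 calls among them. Within the pairs 774 and 773 of the 774 kept the sign, on arrays that had themselves helped to call them. With early or late array serial number as a covariate 379 genes were higher and 404 lower. The counts fell to 101 and 72 on the 7 arrays with early serial numbers alone, to 149 and 248 with genes filtered and probe sets chosen by mean value, and to 182 higher without wild-type replicate 3 and 227 lower without wild-type replicate 1.

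**Figure D2:**
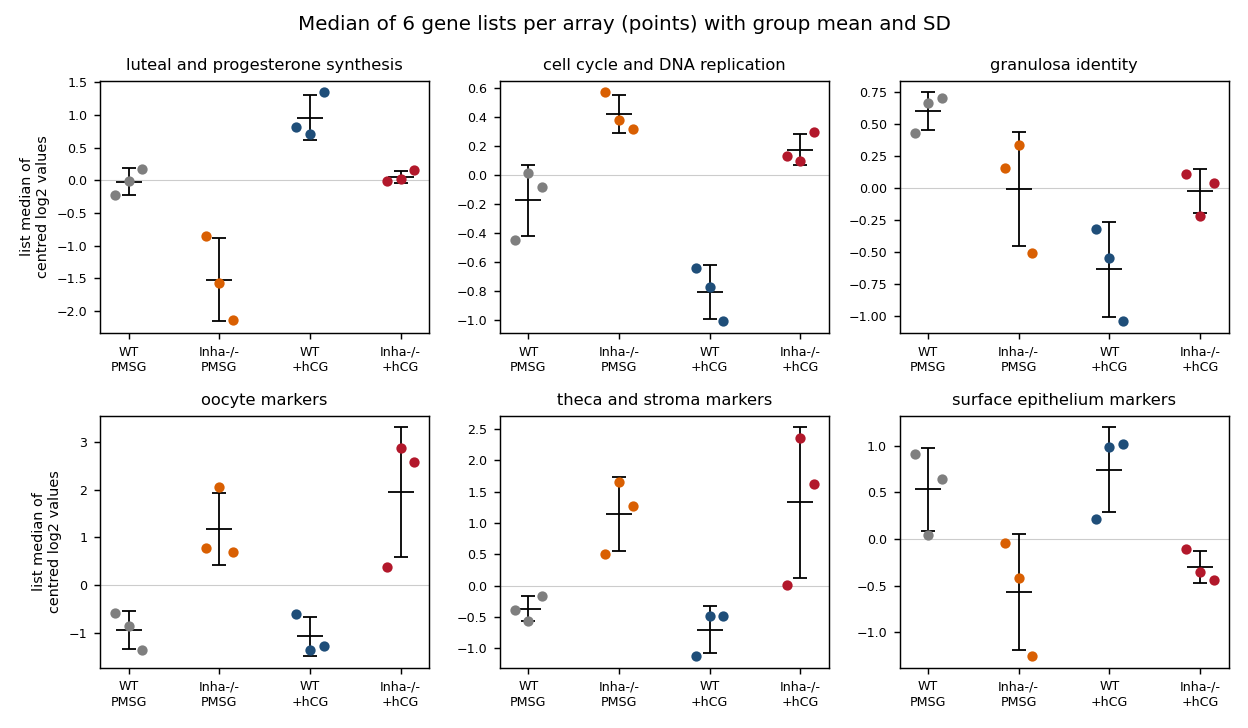
Median centred log2 value (vertical axis) of the measured genes of 6 fixed lists in the 4 groups (horizontal axis), where each point is 1 array and the bars give the group mean and SD of 3 arrays. The oocyte list lay between 0.378 and 2.88 on the knockout arrays and between -1.37 and -0.596 on the wild-type arrays.

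The comparison of knockout with wild type after PMSG and hCG asks what the loss of inhibin alpha changes once the ovulatory signal has been given. Genes that LH induces in the ovulatory follicle were lower in the knockout: Prkg2, a cGMP-dependent protein kinase, was 75.8-fold lower (log2 fold change -6.24 ± 0.235, SE, adjusted p = 8.13e-08), and Snap25, a protein of vesicle fusion, 65.6-fold lower (-6.04 ± 0.333, adjusted p = 1.69e-06). Ptgs2, the prostaglandin synthase of ovulation, was higher (2.64 ± 0.277, adjusted p = 9.27e-05). Of 26 cell cycle genes 18 were higher, and so were single genes of the follicle before the surge, with the cyclin gene Ccnd2 at 3.29 and the inhibin and activin beta subunit gene Inhbb at 3.53. Single oocyte and stroma transcripts were again higher.

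Of the 21 LH-induced ovulatory regulators, 12 fell, 1 rose and 8 did not pass, against 12 and 2 when adjusted over the list alone. Beside Prkg2 and Snap25 the falls included the transcription factor genes Zbtb16 (-5.98) and Runx1 (-3.29), the coactivator gene Cited4 (-3.82, with -0.00573 on its other probe set) and Sult1e1, which sulphates and so inactivates oestrogen (-2.56). Snap25 had -0.70 on its other probe set, those of Zbtb16 gave -4.39 and -0.189, and the other 5 of Runx1 lay between -4.27 and -0.355. The endothelin gene Edn2, whose peptide contracts the follicle wall, fell by 1.80 and the progesterone receptor gene Pgr by 0.73, while the EGF-like ligand gene Ereg rose by 1.22. The other probe sets of Pgr gave -0.0685 and 0.0327, and Pgr turned to 0.57 when the arrays were quantile-normalized again. The list moved down (median -1.18, adjusted p = 1.64e-07, and adjusted p = 0.021 with an estimated correlation). Of 14 genes of cumulus expansion and follicle matrix, 3 rose, 5 fell and 6 did not pass, with 3 and 5 when adjusted over the list alone (adjusted p = 0.18). Ptgs2, the hyaluronan synthase gene Has2 (2.08) and the hyaluronan-linking gene Tnfaip6 (1.47) rose, while the proteases Adamts9 (-3.09), Adam8 (-3.03) and Adamts1 (4.01-fold), the protease inhibitor gene Timp1 (-1.85) and the matrix proteoglycan gene Vcan (-1.65) fell. Without knockout replicate 1 Has2 stood at 1.37 and Timp1 at -1.25, and Vcan, at -1.03, was no longer called. The other 7 probe sets of Vcan lay between -2.47 and -0.00119. Adamts1 was lower in the knockout before hCG too, with group means of -1.50 and -0.0796, against 0.257 and 2.26 after it.

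Of the 12 luteal and progesterone synthesis genes, 6 fell, 1 rose and 5 did not pass, the same counts as when adjusted over the list alone. Falls were those of Akr1c18, which breaks down progesterone (-5.60), Sfrp4 (-5.05), Star (-2.95), Cyp11a1 (-2.29), the cyclin-dependent kinase inhibitor gene Cdkn1a (-1.88) and the lipoprotein receptor gene Scarb1 (-1.19), and the cholesterol transporter gene Npc1 rose by 0.93. The other probe sets of Cyp11a1 gave -0.0668 and 0.0117, and Sfrp4 stood at -4.36 without knockout replicate 1. The list moved down (median -0.85, adjusted p = 0.00242, and adjusted p = 0.351 with an estimated correlation). Of the 26 cell cycle genes 18 rose and 8 did not pass, with 19 rises when adjusted over the list alone, among them the replication helicase gene Mcm3 (2.41), Bub1 (2.30), the cyclin gene Ccne2 (1.83) and the proliferation marker Mki67 (1.41). The other 4 probe sets of Mcm3 lay between 0.551 and 2.05. This list moved up (median 1.10, adjusted p = 4.93e-09, and adjusted p = 0.351 with an estimated correlation).

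Genes of activin signalling and of the FSH-stimulated follicle were called singly, while their lists did not pass in camera. With fry the activin list (adjusted p = 0.00363) and the preantral and cumulus list (adjusted p = 0.0364) moved up and passed. The FSH-induced list did not pass with fry either (adjusted p = 0.117). In the activin list 4 of 14 rose, with 4 when adjusted over the list alone (adjusted p = 0.12): Inhbb, its partner subunit gene Inhba (1.72), the activin-binding protein gene Fst (1.51) and the inhibitory mediator gene Smad7 (1.08). The other probe set of Inhba gave 0.000192. Inhbb, Inhba and Fst fell with hCG in wild type (-3.74, -1.31 and -1.35) and were not called for hCG in the knockout. Of 13 FSH-induced genes 6 rose and 2 fell, with 8 and 2 when adjusted over the list alone (adjusted p = 0.224), among them Ccnd2, the BMP antagonist gene Grem1 (2.34), the oestradiol-forming enzyme gene Hsd17b1 (1.67) and the gap junction gene Gja1 (1.34), while Sgk1 fell by 2.04. Of 11 preantral and cumulus genes 4 rose, with 5 when adjusted over the list alone (adjusted p = 0.113), including Nppc, whose peptide holds the oocyte in meiotic arrest (3.82), and the transcription factor gene Foxo1 (1.40). Other probe sets lay between 0.00578 and 1.18 for Foxo1 and between 0.356 and 0.544 for Gja1. Without wild-type replicate 3 Inhbb stood at 2.30 and Nppc at 2.47. In the BMP and AMH list 3 of 13 rose and 3 fell, with 3 and 3 when adjusted over the list alone (median -0.0106, mean 0.126, adjusted p = 0.897): the receptor genes Bmpr1b (2.07) and Bmpr2 (1.53) rose, and Bmp2 (-2.39) fell. Bmpr1b, at 1.36 without wild-type replicate 3, was no longer called then. Of the panel, Amh (-0.31), Btc, Ptx3 and Fshr (0.66) did not pass, with Btc and Ptx3 between the other 2 genes.

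Oocyte markers stood beside these groups with 9 of 14 genes risen, 5 not past and 12 when adjusted over the list alone (median 3.12, adjusted p = 1.31e-06, and adjusted p = 0.351 with an estimated correlation), led by Zp3 (6.61) and Zp2 (5.72). The median of the oocyte list was 0.378 on knockout replicate 1 and 2.88 and 2.57 on replicates 2 and 3. Of 14 theca and stroma markers 8 rose, 0 fell and 6 did not pass, with 10 when adjusted over the list alone (median 2.20, adjusted p = 0.000243, and adjusted p = 0.351 with an estimated correlation), including Myh11 (3.71), Col1a1 (2.91), Acta2 (2.74) and Gli2 (2.52). The other probe sets of Myh11 and Acta2 gave 0.00359 and -0.00214 to 0.00103. Of 9 epithelium markers 4 fell, with 6 when adjusted over the list alone, among them Krt18 (-2.23) and Krt8 (-1.56) (median -1.32, adjusted p = 8e-04, and adjusted p = 0.363 with an estimated correlation). Of 12 stress genes 2 fell, Dusp1 (-2.58) and the RNA-destabilizing protein gene Zfp36 (-2.64), with 2 when adjusted over the list alone (median -1.43, adjusted p = 0.0161, and adjusted p = 0.577 with an estimated correlation). Leukocyte, endothelial and red blood cell markers had medians of 0.573, -0.268 and -0.557 (adjusted p = 0.113, 0.118 and 0.36).

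After the egg-coat genes, the largest rises were those of Fndc5 (5.40), Srpx2 (5.04), the glutamate receptor gene Grin2c (4.71), the proteoglycan gene Bcan (4.65), the water channel gene Aqp5 (4.65) and the natriuretic peptide receptor gene Npr3 (4.65). After Inha, Prkg2, Snap25 and Zbtb16, the largest falls were those of the hyaluronan receptor gene Lyve1 (-5.81), Akr1c18, Tmem71 (-5.57) and the sphingosine kinase gene Sphk1 (-5.46). Sphk1 had -1.04 on its other probe set, and Lyve1 stood at -5.21 without knockout replicate 1. In limma 1568 genes were higher and 1104 lower in the knockout, 1151 and 811 of them at least 2-fold, and the arrays did not overlap for 40.2% of the genes. A fit with early or late array serial number as a covariate gave 1821 higher and 1229 lower. The counts fell to 952 and 678 without wild-type replicate 3, to 334 and 316 on early and 624 and 437 on late arrays alone, and to 417 and 890 with genes filtered and probe sets chosen by mean value. In this last setting the balance turned, with 31.9% of the calls higher. By construction this filter favours genes raised on few arrays over genes lowered on few arrays, so it does not test the balance. Each of these 2 groups has 1 early array, and the PMSG groups gave the spread there.

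Of the genes called higher after PMSG, 279 were also called higher after hCG, where 46.8 would be shared by independent lists, and of those called lower 187, where 35.4 would be. Across the 12500 genes the fold changes of the 2 comparisons, which share no array, correlated with Pearson's r = 0.574 and Spearman's rho = 0.519. Simulated groups without any effect gave r between -0.53 and 0.53, with a covariance of at most 0.0769 against 0.398 observed.

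The hCG response in wild type shows what the ovulatory signal changed within 6 h. Ovulatory and cumulus genes rose by large factors: Sult1e1 was 4270-fold higher (log2 fold change 12.06 ± 0.269, SE, adjusted p = 3.59e-10), Ereg 278-fold, Ptgs2 267-fold and Pgr 242-fold higher. The other 2 probe sets of Pgr gave 0.00459 and 2.05 on the log2 scale. Star was higher by 7.04 on the log2 scale. Of 26 cell cycle genes 10 were lower, and so were single genes of the follicle before ovulation, with the oocyte-arresting peptide gene Nppc 14.4-fold (-3.85 ± 0.841, adjusted p = 0.00744) and Inhbb 13.3-fold lower (-3.74 ± 0.76, adjusted p = 0.00525). Without wild-type replicate 3 after hCG the fall of Nppc was -2.50 and that of Inhbb -2.51. The other-cell markers showed no list past the threshold.

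Of the 21 LH-induced regulators 14 rose and 7 did not pass, with 14 when adjusted over the list alone, among them Prkg2 (9.34), the EGF-like ligand gene Btc (8.82), Ereg (8.12) and Runx1 (6.37). The other 5 probe sets of Runx1 lay between 0.234 and 6.02. The list moved up (median 4.34, adjusted p = 1.1e-17, and adjusted p = 0.000959 with an estimated correlation). Of the 14 cumulus expansion and matrix genes 13 rose and 1 did not pass, with 13 when adjusted over the list alone: Ptgs2, the pentraxin gene Ptx3 (7.53, with 0.0446 on its other probe set), Tnfaip6 (7.41), Adamts9 (5.32) and Has2 (4.52) led them (median 3.69, adjusted p = 5.47e-16, and adjusted p = 0.000992 with an estimated correlation). Of the 12 luteal genes 6 rose and 6 did not pass, against 6 rises and 1 fall when adjusted over the list alone, with Akr1c18 at 4.32 and Cdkn1a at 3.31 (median 1.14, adjusted p = 0.000678, and adjusted p = 0.307 with an estimated correlation). Of the 19 cholesterol synthesis genes 8 rose and 11 did not pass, with 9 when adjusted over the list alone, led by Hmgcs1 (2.54) and the demethylase gene Cyp51 (2.00) (median 0.695, adjusted p = 0.000165, and adjusted p = 0.449 with an estimated correlation).

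Of the 26 cell cycle genes 10 fell and 16 did not pass, with 13 when adjusted over the list alone, including the cyclin gene Ccnb2 (-1.59), Mki67 (-1.20) and the mitotic cyclin gene Ccna2 (-0.82) (median -0.669, adjusted p = 0.000678, and adjusted p = 0.496 with an estimated correlation). Of the 13 granulosa identity genes 6 fell, 1 rose and 6 did not pass, against 8 and 1 when adjusted over the list alone, with the forkhead factor gene Foxl2, which maintains granulosa cell fate, at -3.97, the oestrogen receptor gene Esr2 at -2.48 and the FSH receptor gene Fshr at -1.91, while the WNT ligand gene Wnt4 rose by 1.82 (median -1.30, adjusted p = 0.0034, and adjusted p = 0.307 with an estimated correlation). Of the 11 preantral and cumulus genes 4 fell and 7 did not pass, with 5 when adjusted over the list alone, among them Foxo1 (-2.02, with -1.86 to -0.00457 on its other probe sets) and the natriuretic peptide receptor gene Npr2 (-1.68) (median -0.926, adjusted p = 0.0034, and adjusted p = 0.423 with an estimated correlation). The activin list (adjusted p = 0.559) held 4 falls and 1 rise among 14 genes, with 4 and 1 when adjusted over the list alone: Inhbb, the coreceptor gene Tgfbr3 (-2.10), Fst (-1.35) and Inhba (-1.31, with 0.00481 on its other probe set) fell, and the receptor gene Acvr1 rose by 0.83, with 0.0339 and 0.473 on its other probe sets. The FSH-induced list (adjusted p = 0.291) held 7 falls and 2 rises among 13 genes, against 7 and 4 when adjusted over the list alone, with Hsd17b1 at -1.78 and Sgk1 risen. Of the panel, Amh (-0.69), Inha and Cyp11a1 (0.49) did not pass, and the group mean of Adamts1 rose from -0.0796 to 2.26.

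The largest rises outside these lists were those of the neuropeptide genes Nts (11.88) and Nmu (8.38), the ubiquitin ligase gene Rnf125 (8.16) and the EGF-like ligand gene Epgn (7.84). The largest falls outside these lists were those of the semaphorin receptor gene Plxnc1 (-3.97), Tmem25 (-3.68) and Psd (-3.67). Without wild-type replicate 3 after hCG these were -3.31, -2.93 and -2.50, and Foxl2, at -2.97, was no longer called. Of the other 5 probe sets of Plxnc1, 4 had the same sign and 1 gave 0.00131. In limma 1234 genes were higher and 1530 lower, 956 and 1077 of them at least 2-fold, and the arrays did not overlap for 43.2% of the genes. The late-numbered arrays hold no wild type before hCG, and early or late number as a covariate gave 1027 higher and 1274 lower. Without wild-type replicate 3 after hCG, where Inhbb stood at -6.04 against -2.16 and -2.54 on the other 2 arrays, 814 genes were higher and 724 lower, while 603 and 626 were called on early arrays alone. These hold 1 wild-type array after hCG, assumed to vary like the PMSG groups. Array quality weights gave 1971 higher and 2572 lower, and genes filtered and probe sets chosen by mean value gave 997 higher and 390 lower. In this last setting the balance turned, with 71.9% of the calls higher. This filter favours by construction genes raised on few arrays over genes lowered on few arrays, so it does not test the balance.

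**Figure D3:**
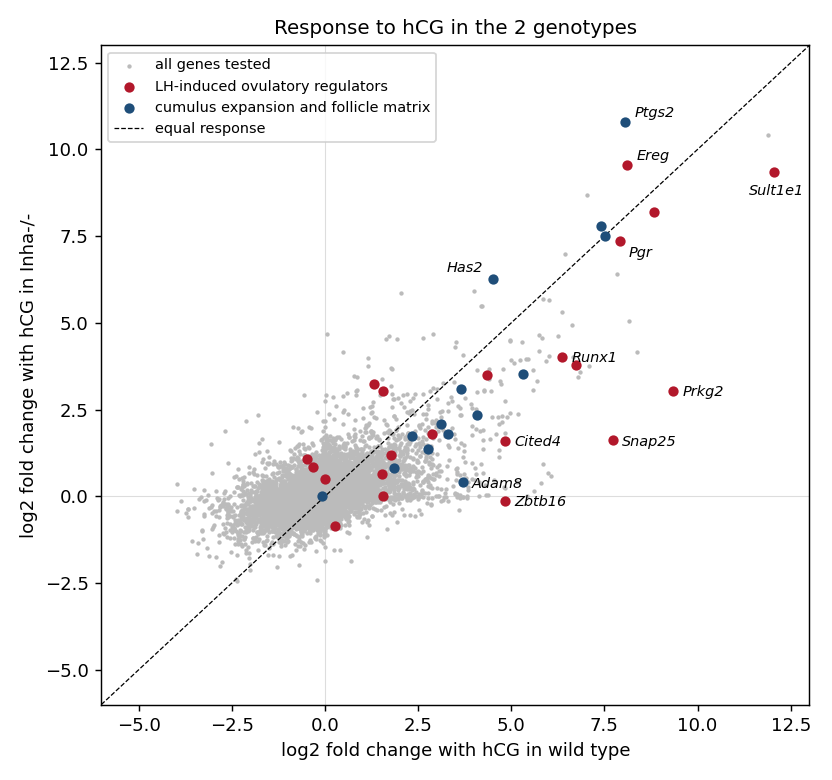
Log2 fold change with hCG in wild type (horizontal axis) and in the Inha knockout (vertical axis) for each of the 12500 genes tested (grey points), with LH-induced ovulatory regulators in red and genes of cumulus expansion and follicle matrix in blue. The dashed line marks equal responses: Ptgs2 lies above it at 8.06 and 10.78, and Prkg2 below it at 9.34 and 3.04.

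The hCG response in the knockout asks the same of cells without inhibin alpha. Ovulatory and cumulus genes rose here too: Ptgs2 was 1760-fold higher (log2 fold change 10.78 ± 0.277, SE, adjusted p = 1.12e-09), Ereg 745-fold, Sult1e1 654-fold and Star 412-fold higher. Has2 rose by 6.27 (5.56 without knockout replicate 1 after hCG) and Pgr by 7.37, with 0.00481 and 1.94 on its other probe sets. Few genes were called lower, and the largest called fall was that of Igfbp1, a binding protein of insulin-like growth factors (-1.99 ± 0.332, adjusted p = 0.00656). Genes of the cell cycle, of granulosa identity and of the preantral follicle had no called fall.

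Of the 21 LH-induced regulators 12 rose, 1 fell and 8 did not pass, against 13 and 1 when adjusted over the list alone, with Btc at 8.21, Runx1 at 4.02 (-0.0225 on 1 of its other 5 probe sets) and Prkg2 at 3.04 (-0.0256 on 1 of its other 2), and the fatty acid receptor gene Pparg at -0.84 (median 1.79, adjusted p = 2.3e-21, and adjusted p = 0.000279 with an estimated correlation). Of the 14 cumulus and matrix genes 8 rose and 6 did not pass, with 11 when adjusted over the list alone, among them Tnfaip6 (7.79) and Ptx3 (7.50, with -0.0768 on its other probe set) (median 2.21, adjusted p = 3.32e-22, and adjusted p = 0.000279 with an estimated correlation). Of the 12 luteal genes 6 rose and 6 did not pass, with 6 when adjusted over the list alone: Star, Ptgfr (3.45, with 0.105 to 3.38 on its other probe sets), Fdx1 (3.39), Sfrp4 (2.88), Cdkn1a (2.68, with 0.437 on its other probe set, and 2.01 and not called without knockout replicate 3 after PMSG) and Cyp11a1 (1.43, with -0.265 and -0.0689 on its other probe sets) (median 1.31, adjusted p = 4.59e-09, and adjusted p = 0.0428 with an estimated correlation). Of the 19 cholesterol genes 3 rose, with 4 when adjusted over the list alone, led by Hmgcs1 (1.47, with 0.357 to 0.555 on its other probe sets) (median 0.463, adjusted p = 1.36e-05, and adjusted p = 0.366 with an estimated correlation). The FSH-induced list held 3 rises among 13 genes, with 3 when adjusted over the list alone (median 0.264, adjusted p = 0.0215, and adjusted p = 0.387 with an estimated correlation). These were Fdx1, the immediate early factor gene Nr4a1 (3.25) and Sgk1 (1.68), genes that LH also raises.

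The cell cycle list held 0 called genes among 26, singly or when adjusted over the list alone, and moved down (median -0.23, adjusted p = 0.0292, and adjusted p = 0.581 with an estimated correlation). The WNT list held 3 rises among 14 genes, with 4 when adjusted over the list alone, namely Sfrp4, Wnt4 (1.79) and the receptor gene Fzd1 (1.13) (median 0.555, adjusted p = 0.00118, and adjusted p = 0.207 with an estimated correlation). The lists of TGF-beta-responsive matrix genes and of leukocyte markers held 0 called genes and moved up (medians 0.596 and 0.468, adjusted p = 0.00116 and 0.0189, and adjusted p = 0.421 and 0.581 with an estimated correlation). Of 12 stress genes 1 rose, the AP-1 gene Junb (4.55, and 3.86 without knockout replicate 1 after hCG and 3.93 without knockout replicate 3 after PMSG, not called in both), with 3 when adjusted over the list alone (median 0.937, adjusted p = 0.000644, and adjusted p = 0.435 with an estimated correlation). Oocyte, theca and stroma, and epithelium markers held 0 called genes (medians 0.588, 0.18 and 0.252, adjusted p = 0.089, 0.9 and 0.165). Of the panel, Inha, Inhba, Inhbb and Fst did not pass, nor did Fshr (-0.60) and Amh (0.67), between which Inhba, Inhbb and Fst lay. The group mean of Adamts1 rose from -1.50 to 0.257.

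In limma 306 genes were higher and 28 lower, 295 and 20 of them at least 2-fold, so that 91.6% of the called genes were higher, and 77.8% when the arrays were quantile-normalized again. Beside Igfbp1 the largest falls were those of Etl4 (-1.86), Rnf144b (-1.72), the death receptor gene Eda2r (-1.71) and Pdk4, a kinase that restrains pyruvate oxidation (-1.56), and the immediate early gene Egr3 rose by 6.98, with -0.0147 on its other probe set. Other probe sets lay between -0.486 and -0.0462 for Etl4 and between -0.481 and -0.188 for Rnf144b. The arrays did not overlap for 15.6% of the genes. Early or late number as a covariate gave 307 higher and 33 lower. The count of falls went from 8 without knockout replicate 2 after hCG to 59 without knockout replicate 3 after PMSG, and to 98 when quantile-normalized again, while the count of rises went to 139 with only these 2 groups in the fit, to 97 on early arrays alone and to 183 with genes filtered and probe sets chosen by mean value. The early arrays hold 1 knockout array after hCG, assumed to vary like the PMSG groups.

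The interaction asks whether the response to hCG differed between the genotypes. Part of the LH-induced program rose less in the knockout: the log2 response in the knockout minus that in wild type was -6.30 ± 0.332 (SE, adjusted p = 7.02e-06) for Prkg2, -6.10 for Snap25, -4.97 for Zbtb16 and -4.28 for Akr1c18. Snap25 had -0.832 on its other probe set, and those of Zbtb16 gave -3.09 and -0.594. Ptgs2 rose more (2.73 ± 0.392, adjusted p = 0.004). Fst, which fell in wild type, differed by 1.56 ± 0.337 (adjusted p = 0.0405), and so did the receptor gene Bmpr2 (2.06) and the kinase subunit gene Prkar2b (2.03). These 3 genes lost the call when any of several single arrays was left out.

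Of the 21 LH-induced regulators 6 had a lower response in the knockout and 15 did not pass, against 8 lower and 1 higher when adjusted over the list alone, and the others were Cited4 (-3.24, with -0.0115 on its other probe set), Sult1e1 (-2.70) and Edn2 (-1.57) (median -0.872, adjusted p = 2.24e-07, and adjusted p = 0.0195 with an estimated correlation). Of the 14 cumulus and matrix genes Ptgs2 was higher and Adam8 lower (-3.30), with 1 and 1 when adjusted over the list alone (adjusted p = 0.0573). The FSH-induced list had 2 higher responses among 13 genes, Prkar2b and Fdx1 (1.84), with 7 when adjusted over the list alone (median 1.71, adjusted p = 0.000216, and adjusted p = 0.21 with an estimated correlation). Fdx1 started lower in the knockout, between -3.31 and -3.07 after PMSG against -1.37 to -0.147 in wild type. The granulosa identity list had 1 among 13, Fst, with 5 when adjusted over the list alone (median 1.31, adjusted p = 0.000294, and adjusted p = 0.21 with an estimated correlation). The preantral list had 0 among 11, with 4 when adjusted over the list alone (mean 1.24, adjusted p = 0.00291, and adjusted p = 0.261 with an estimated correlation). The BMP list had 1 among 13, Bmpr2, with 1 when adjusted over the list alone (median 0.931, adjusted p = 0.0306, and adjusted p = 0.261 with an estimated correlation), and the cell cycle list 0 among 26 in both counts (median 0.461, adjusted p = 0.0207, and adjusted p = 0.709 with an estimated correlation). Oocyte, theca and stroma, and epithelium markers had 0 called genes (medians 0.833, 0.754 and 0.171, adjusted p = 0.0961, 0.225 and 0.841). Of the panel, 14 genes did not pass, between Btc (-0.61) and Inhbb (3.25).

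In limma 73 genes had a higher and 188 a lower response in the knockout, all of at least 2-fold. Of the 188, 186 rose with hCG in wild type and 29 in the knockout, and of the 73, 52 fell in wild type and 21 rose in the knockout. The largest positive differences were those of the polo-like kinase gene Plk2 (4.61, with -0.0229 on its other probe set), Npr3 (3.84), the cholesterol hydroxylase gene Ch25h (3.67) and Fndc5 (3.17), and the largest negative ones after Prkg2 and Snap25 those of Sphk1 (-5.48), Tmem71 (-5.46) and the glucagon gene Gcg (-5.43). Sphk1 had -1.06 on its other probe set, and Plk2 stood at 3.80 without knockout replicate 1 after hCG. Across the 12500 genes the responses in the 2 genotypes, which share no array, correlated with r = 0.624 and rho = 0.515, where simulated groups without effect gave r up to 0.64 and a covariance of at most 0.0926 against 0.426 observed. Early or late number as a covariate gave 64 higher and 165 lower. The count of higher responses went from 25 without wild-type replicate 2 after PMSG to 286 without wild-type replicate 2 after hCG, and to 12 with a trended and robust variance, 195 with array quality weights and 16 on early arrays alone. Each hCG group has 1 early array, and the PMSG groups gave the spread there. The count of lower responses went to 111 without wild-type replicate 2 after PMSG, 84 with a trended and robust variance and 56 on early arrays alone.

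The effect of genotype after PMSG and the hCG response in wild type share the wild-type arrays after PMSG, so that chance alone ties their values. Their fold changes correlated with r = 0.0985 and rho = 0.0833 across genes, against a mean of 0.44 in simulated groups without effect, and the covariance was 0.0734 against 0.073 simulated, a difference of 0.000133. Of the genes called lower in the knockout after PMSG 149 were called lower with hCG in wild type, where 49.1 would be shared by independent lists, and of those called higher 69 were called higher, where 36.8 would be. The 3 shared arrays are too few to be split into parts of at least 2, so part of this excess may come from the shared arrays.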

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

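Of the tests in this part, the one on late-numbered arrays and the reading of levels before hCG by quartile were chosen after the result was seen.

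The interaction between genotype and hCG singled out the genes below, because their response differed between the groups. Their values are log2 responses in the knockout minus those in wild type. Higher responses were found for Plk2 (4.61), Npr3 (3.84), Ch25h (3.67), Fndc5 (3.17), Fbn2 (3.09), Dhh (3.09), Ptgs2 (2.73), Aqp5 (2.51), Bmpr2 (2.06), Prkar2b (2.03), Fdx1 (1.84) and Fst (1.56). Lower responses among LH-induced and cumulus genes were found for Prkg2 (-6.30), Snap25 (-6.10), Zbtb16 (-4.97), Adam8 (-3.30), Cited4 (-3.24), Sult1e1 (-2.70) and Edn2 (-1.57). Other lower responses were those of Sphk1 (-5.48), Tmem71 (-5.46), Gcg (-5.43), Asgr1 (-5.41), Hhip (-4.97), Lyve1 (-4.58), Akr1c18 (-4.28), Nmu (-4.20), Fzd1 (-3.55), Rbp4 (-3.44), Rnf125 (-3.10), Rhox5 (-2.98), Etl4 (-2.55), Epgn (-1.42) and Cyp26b1 (-1.13). The other 5 probe sets of Etl4 lay between -2.15 and -0.0404. Some genes differed by genotype before hCG, so their interaction also reflects the starting level. After PMSG Hhip lay between 0.02 and 1.43 in the knockout and between -5.31 and -3.48 in wild type. Rbp4 lay between -0.14 and 0.89 against -4.55 and -3.77, and Fdx1 between -3.31 and -3.07 against -1.37 and -0.147. Lyve1 varied among the wild-type arrays after PMSG (0.25, -1.08 and 2.02).

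The interaction also singled out 6 lists in camera: LH-induced regulators (adjusted p = 2.24e-07) with a lower response in the knockout, and FSH-induced genes (adjusted p = 0.000216), granulosa identity (adjusted p = 0.000294), preantral and cumulus genes (adjusted p = 0.00291), the cell cycle (adjusted p = 0.0207) and BMP signalling (adjusted p = 0.0306) with a higher one. With an estimated correlation the LH-induced list kept its call (adjusted p = 0.0195), and the other 5 lost it, at adjusted p = 0.21, 0.21, 0.261, 0.709 and 0.261 in this order.

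Probe sets that name no gene or several hold signal that the gene tables leave out. They were counted in the fit of all probe sets one by one, with p values adjusted over all of these. Of 4176 such probe sets limma called 661 for knockout against wild type after hCG and 516 for the hCG response in wild type.

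Few genes were called lower with hCG in the knockout, 28 against 1530 in wild type. This count of calls is no absence of falls. Of the 1530 genes, 1293 (84.5%) had a negative log2 fold change in the knockout too, with a median of -0.303. In the interaction 52 of the 1530 were called. A wider spread among the knockout arrays was tested by choosing falling genes on 2 wild-type arrays per group and reading the left-out arrays: the median response, averaged over 9 choices, was -1.34 in held-out wild type and -0.329 in the knockout, smaller in 9 of 9, which this explanation does not give. Late-numbered wild-type arrays could make the fall, but the early-numbered one gave -1.15, and genes chosen as rising in wild type rose less in the knockout as well, 0.518 to 0.808 against 1.28 to 2.92 in held-out wild type, while Ptgs2 rose more (10.78 against 8.06). Levels already low in the knockout before hCG could leave less to fall: the median difference averaged -0.00191, from -0.1 to 0.0767 over the 9 choices and in 4 below the 5th percentile of random genes, but single genes went both ways, and the missing fall lay beyond their lower quartile in only 6 of 9, so the bound set before on the median was too loose. For part of the genes a low level before hCG and a weaker response to it cannot be told apart here, and the share of other cells in the samples was not separated from either.

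The 6 arrays of a comparison split into 3 and 3 in 10 ways, the real one included, too few for a share under 0.05. The real split gave the highest count each time, 1 of 10, here beside the highest other count: 774 calls against 26 for the genotype effect after PMSG, 2672 against 0 after hCG, 2764 against 0 for the hCG response in wild type, and 334 against 29 for that in the knockout. For the interaction 4 of 100 splits reached the 261 calls, the real one and 3 others, which gave up to 1208. All 3 kept the hCG arrays apart by genotype and, relative to them, exchanged the genotype of 2 of the 3 PMSG arrays of each group.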

How the results depend on the processing

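Of the alternatives below, the narrower spread filter and the fits on early or on late arrays alone were chosen after the data were seen. The filter and probe choice by mean value was added then too, but is the rule planned for centred values. The spread filter and probe choice of the main fit were themselves chosen after the values were seen.

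Of 8766 values of named genes under 32 other settings, 7449 kept direction and side of the threshold, 1287 kept the direction but were no longer called, 10 became called and 20 reversed. Genes that a setting dropped are not in this tally. Of 347 values followed, the filter and probe choice by mean value kept 178, weakened 51, reversed 11 and dropped the others. In the order of the contrasts it shared 317 of 774 main calls, 1089 of 2672, 1142 of 2764, 166 of 334 and 173 of 261. Of 1073 list results 960 stayed and 113 were no longer past the threshold. The planned filter at a log2 value of at least 6 was not run, since the values are centred. Arrays lack a measured background here, which limits what can be said of weak genes.

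With the filter and probe choice by mean value another probe set stood for these genes, which by construction gave reversed values: Nr5a1 0.136, Cyp11a1 0.164 and Ptgfr 0.0154 for the genotype effect after PMSG, Cyp11a1 0.0117 after hCG, Cyp11a1 -0.113, Tgfb1 -0.0367, Inhba 0.00481, Mcm3 0.00162 and Zfp385b 0.017 for hCG in wild type, and Cyp11a1 -0.265 and Ptx3 -0.0768 for hCG in the knockout. Quantile normalization reversed Pgr (0.569, genotype after hCG) and Cyp11a1 (-0.0665, hCG in wild type). Amh, never called, ranged from -1.18 to 0.374 with an array left out for genotype after hCG (0.374 without WT_PMSG_hCG replicate 1, 0.262 without InhaKO_PMSG_hCG replicate 1) and was 0.946 on late arrays. For hCG in wild type Amh ranged from -1.55 to 0.45 (0.45 without WT_PMSG replicate 1) and was 0.681 on early arrays. For hCG in the knockout Amh ranged from -0.200 to 1.24 (-0.200 without InhaKO_PMSG_hCG replicate 2) and was -0.0409 on early arrays. For these the cause was not tested.

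Counts are given as higher and lower, in the order genotype after PMSG (main 373 and 401), genotype after hCG (1568 and 1104), hCG in wild type (1234 and 1530), hCG in the knockout (306 and 28) and interaction (73 and 188), and only where they moved more than 1.5-fold. All probe sets, which are more than the genes, gave 603 and 761, 2638 and 2598, 2544 and 2548, 536 higher, and 126 and 401. An adjusted p under 0.01 gave 139 and 154, 823 and 587, 774 and 651, 177 and 5, and 10 and 80. Only the 2 groups compared, with fewer arrays, gave 229 and 233 after PMSG and 139 and 3 for hCG in the knockout. The 4 arrays with a shared name number gave 0 and 0 after PMSG in limma, with 1 residual degree of freedom and 1654 genes at an unadjusted p under 0.05, while the number as a random block over all arrays gave 545 and 561, all 774 calls among them. The mean-based filter gave 149 and 248, 417 and 890, 997 and 390, 183 and 18, and 33 higher, so that the balance turned for genotype after hCG (31.9% of calls higher) and for hCG in wild type (71.9%). A mean of values centred on their median is higher for a gene raised on few arrays than for one lowered on few. This filter therefore favours the former by construction and does not test the balance. Early arrays alone gave 101 and 72, 334 and 316, 603 and 626, 97 higher, and 16 and 56, and late arrays alone 624 and 437 (genotype after hCG) and 48 lower (hCG in the knockout), both with fewer arrays. Early arrays hold 1 array of each hCG group and late arrays 1 of the knockout after PMSG, and a lone array was assumed to vary like the other groups. Array weights gave 1971 and 2572 for hCG in wild type and 195 higher for the interaction. For the interaction the mean of all probe sets gave 130 higher, a random block 48 higher, and a trended and robust variance 12 and 84. Quantile normalization gave 98 lower for hCG in the knockout (77.8% of calls higher, against 91.6%) and a correlation of 0.281 between the genotype effect after PMSG and hCG in wild type. Unless stated, the cause was not tested.

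List counts (main 9, 7, 7, 10 and 6) became 0, 1, 2, 3 and 1 with an estimated correlation. Fry gave 11 for genotype after hCG and 4 for hCG in the knockout, and no filter gave 16 for hCG in the knockout. For genotype after hCG the activin, preantral, granulosa identity, Sertoli and hypoxia lists passed by fry and not by camera. Their fry adjusted p values were 0.00363, 0.0364, 0.0402, 0.022 and 0.0307. Stress genes passed by camera and not by fry (adjusted p = 0.202). In the interaction the activin list passed by fry (adjusted p = 0.0155) and not by camera (adjusted p = 0.0808). The cause was not tested.

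With each array left out, genotype after PMSG gave 182 to 441 higher (182 without WT_PMSG replicate 3, 216 without replicate 2, 248 without replicate 1) and 227 to 501 lower (227 without WT_PMSG replicate 1, 250 without replicate 3, 267 without InhaKO_PMSG replicate 2, 244 without replicate 3). Genotype after hCG gave 952 to 1773 higher and 678 to 1238 lower, both lowest without WT_PMSG_hCG replicate 3. Without this array hCG in wild type was lowest too, at 814 to 1349 higher and 724 to 1835 lower (975 without WT_PMSG replicate 1, 967 without replicate 2). For hCG in the knockout 206 to 359 were higher and 8 to 59 lower (8 without InhaKO_PMSG_hCG replicate 2, 15 without replicate 1, 14 without WT_PMSG replicate 2, 17 without replicate 3, 17 without WT_PMSG_hCG replicate 1, 59 without InhaKO_PMSG replicate 3). The interaction gave 25 to 286 higher (25 without WT_PMSG replicate 2, 42 without replicate 1, 30 without replicate 3, 47 without InhaKO_PMSG replicate 2, 35 without replicate 3, 286 without WT_PMSG_hCG replicate 2, 35 without replicate 3, 30 without InhaKO_PMSG_hCG replicate 2, 34 without replicate 3) and 111 to 263 lower (111 without WT_PMSG replicate 2, 118 without replicate 3). Lists numbered 8 to 10, 6 to 11 (11 without InhaKO_PMSG_hCG replicate 1), 7 to 8, 6 to 11 (6 without InhaKO_PMSG replicate 1) and 5 to 11 (11 without InhaKO_PMSG replicate 2). The correlations ran from 0.514 to 0.612 for the genotype effects, 0.556 to 0.641 for the hCG responses and 0.0494 to 0.137 for the pair with shared arrays. The cause was not tested.

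Replicate numbers were not taken to pair the samples, since not every pair correlated over 0.1: deviations of the same number correlated over 0.1 in 2 of 3 for genotype after PMSG, 1 for genotype after hCG, 2 for hCG in wild type and 0 for hCG in the knockout. The 2 pairs after PMSG (0.18 and 0.3) are those that share an array-name number, and 6 of 6, 2 of 6, 6 of 6 and 2 of 6 samples correlated best with their own number. A replicate block called 755, 2683, 2813, 324 and 247 genes, 657, 2469, 2574, 288 and 206 of them shared with the main result.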

Other observations

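Of the tests in this part, those on the share of granulosa cells, on theca cells and on the neighbours of Inha were chosen after the result was seen.

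Lists that the comparisons above left out held single genes of interest. Of 10 measured Sertoli cell genes, markers of the testicular counterpart of granulosa cells, 1 was higher and 4 were lower in the knockout after hCG, with the same counts when adjusted over the list alone (adjusted p = 0.113): Dhh, a hedgehog ligand, was higher by 3.81, and the homeobox gene Rhox5 (-3.18), the defensin gene Defb19 (-1.86), the cystatin gene Cst9 (-1.15) and the prostaglandin D synthase gene Ptgds (-1.09) were lower. Dhh fell with hCG in wild type (-3.67). In the knockout it lay between -0.06 and 1.23 after PMSG and between 0.02 and 0.41 after hCG. Defb19 already lay between -1.33 and -0.54 in the knockout after PMSG, against 0.754 to 1.08 in wild type. Of 14 hypoxia and angiogenesis genes 4 fell in the knockout after hCG, with 4 when adjusted over the list alone (adjusted p = 0.113), among them Ndrg1 (-1.76), the vessel-destabilizing ligand gene Angpt2 (-1.54) and the vasodilator gene Adm (-1.44). The other probe sets of Angpt2 and Adm gave -0.048 and -0.26. After PMSG 1 of the 14 genes was already lower, Angpt2 (-2.43, with -0.228 on its other probe set). The oxygen sensor gene Egln3 rose with hCG by 6.01 in wild type and by 5.67 in the knockout. Of 17 matrix genes 6 rose and 2 fell in the knockout after hCG, against 7 and 2 when adjusted over the list alone (adjusted p = 0.113), the collagen genes Col1a2 (3.25) and Col3a1 (1.96) rising and the matricellular genes Ccn1 (-4.59) and Ccn2 (-2.26), targets of YAP, falling. On the other probe sets Col1a2 had 0.0368 and 2.95. After PMSG 4 of the 17 genes were already higher and 2 lower, among them Col1a2 (2.81), Col3a1 (1.80) and Ccn1 (-3.70). The other probe sets of Col1a2 gave 0.538 and 2.03 there. Ccn2 lay between -1.84 and -0.615 in the knockout after PMSG and between 1.55 and 2.51 in wild type.

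Of 14 WNT genes 2 rose and 3 fell in the knockout after PMSG, against 3 and 3 when adjusted over the list alone (median 0.0917, mean -0.211, adjusted p = 0.743), with the WNT antagonist gene Sfrp1 at 2.33 and the R-spondin receptor gene Lgr5 at -1.81. The other probe set of Lgr5 gave 0.0634, and those of Sfrp1 lay between 0.00788 and 1.34. Lgr5 stood at -1.18 without wild-type replicate 3, and Sfrp1, at 1.75 without knockout replicate 3, was no longer called then. Median and mean also differed in sign for the WNT list in the hCG response of wild type (-0.208 and 0.231), for endothelial (-0.00519 and 0.12) and red blood cell markers (-0.0873 and 0.31) in that of the knockout, and for hypoxia genes in the interaction (0.0129 and -0.0776). Of 12 apoptosis genes 1 rose in the hCG response of wild type, the growth arrest gene Gadd45a (1.22), with 1 when adjusted over the list alone (adjusted p = 0.346).

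Markers of oocytes, theca and stroma, and epithelium differed by genotype. A lower share of granulosa cells in the knockout samples would raise every other list if the other cell types rose together. The lowest list median after PMSG was -1.46, for epithelium. The other cell types need not change together, so this test cannot decide on the share of granulosa cells. Oocytes carried into the knockout samples could raise oocyte markers, and a second list of 15 oocyte genes was fixed before its values were read. It had a median of 0.644 after PMSG and 1.79 after hCG, at the 100th percentile of 10000 random lists. In both comparisons 14 of 15 genes were positive, with 1 and 8 called and Bcl2l10 at 2.89 and 3.60. Random genes do not vary together as oocyte genes do (estimated correlation 0.67 in the first oocyte list). The percentile therefore overstates the certainty. Androgen-making theca cells carried in would raise Cyp17a1 if its expression per cell were the same in both genotypes. Cyp17a1 stood at -2.94, but this single gene may itself depend on genotype, so the test cannot exclude theca cells. The second oocyte list moved with the first, as carried-in oocytes would give, and bears on the oocyte markers alone. More oocyte RNA for any other reason would move it too, so this test cannot decide on carried-in oocytes. Whether theca cells were carried in stays open. What set the stroma and epithelium markers apart was not found.

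Obsl1, the gene next to Inha, was lower in the knockout (-4.24 after PMSG, adjusted p = 9.94e-05, and -2.52 after hCG, adjusted p = 0.000681), while its other 4 probe sets gave -2.10 to 0.159 and -1.11 to 0.481. Linked DNA around the targeted allele could change neighbouring genes: of the 20 tested genes nearest to Inha, without Inha and Obsl1, 6 were called, where windows of the same size held a median of 5 and a 95th percentile of 8. An effect of linked DNA and an effect of inhibin loss cannot be told apart here.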
